A study of Homo sapiens with 4 samples.

How the data were processed

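Poly(A) RNA of HUES8 human embryonic stem cells, WT and TET1/TET2/TET3 triple knockout, 2 libraries each, was sequenced with a non-stranded TruSeq kit, per the labels' protocols. Cells were cultured on irradiated mouse embryonic fibroblast feeders, per the same protocols. The deposited values are whole-number counts per Ensembl gene ID, 63677 genes per library, followed by 5 summary lines in the layout of htseq-count. The submitters' processing notes name Bowtie, HTSeq 0.6.0, DESeq2 1.4.5 and genome build hg19, without saying which step each did. The annotation release, the counting mode and the treatment of unaligned reads are not given in the sources used here. All deposited counts were unnormalised. Bowtie does not align across splice junctions, and which version was used is not given.

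The summary lines held 41.6%, 39.8%, 29.6% and 39.4% of all entries in WT replicates 1 and 2 and TKO replicates 1 and 2. Reads outside genes were 9.98%, 9.71%, 6.31% and 10.8% of uniquely aligned reads. TKO replicate 1 was the 1 library with 0 reads listed as not aligned. Titles decide the replicate numbers used here, and for TKO they run opposite to the numbers in the deposited names. Both TKO libraries carry the same genotype, so the comparison of TKO with WT does not use the numbers. The fits with a term for the replicate number, and the overlap in which each TKO library is set against the WT library of its own number, do depend on them.

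Gene symbols were matched to 52526 IDs, with biotypes and chromosome names from GENCODE 29, which is built on another assembly, so no coordinates are given. Of 804 listed symbols 772 matched and 649 were tested. Y-linked genes, XIST and TSIX (474 IDs) were left out of every fit and table. Genes were kept by edgeR's filterByExpr at its default settings (21584 genes). Counts were scaled by the trimmed mean of M values and compared with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood F tests, TKO against WT, and Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values are given as mean ± SD of 2 libraries, and differences of single libraries on the log2 scale used a prior count of 2. An exact permutation test of 2 against 2 cannot give a p under 0.333, so the model across genes was used. With 2 libraries per group, 2 residual degrees of freedom remained. Replicate numbers did not pair the libraries: the within-group deviations of same-numbered libraries had a correlation of -0.04 across 21584 genes.

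Gene lists (25, of which 24 could be tested) were fixed with their members before the data were examined, and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Adjusted p of lists are over the 24 lists. With an estimated correlation camera rests on the residual degrees of freedom, 2 here. A failure in that test therefore does not show that a list is unchanged. The fixed rule for named genes took TET1, TET2 and TET3, the 12 largest rises and 12 largest falls among genes past the adjusted threshold with at least 1 CPM on average and no overlap between groups, and up to 4 members of each list with the smallest p. edgeR gave 0 such genes, so the rises and falls were taken with DESeq2's adjusted p (383 higher and 267 lower genes met it), a choice made after the data were seen. Genes named outside the rule are said to be so where they appear.

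Where a group summed to 1 to 3 counts, the ratio of the groups is given with an exact 95% counting interval. Where it summed to 0, a floor of 3 counts over the group was used. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Total gene counts of 76328879 to 92846815 per library make counting error small for genes above a few CPM.

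Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, scaling by relative log expression and by the upper quartile, no filter on low counts, a filter of 1 CPM in at least 2 libraries, a term for the replicate number, and each library left out in turn. Added after the data were seen were a newer quasi-likelihood estimator, a robust prior, protein-coding genes alone, and for DESeq2 each library left out in turn, protein-coding genes alone and the replicate term. The tests were checked on simulated counts for 21584 genes with 200 changed genes, 50 at each fold size.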

Results

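RNA was measured by poly(A) sequencing in HUES8, an established human embryonic stem cell line, as 2 wild type (WT) libraries and 2 libraries of a TET1, TET2 and TET3 triple knockout (TKO) of the same line. TET enzymes oxidise 5-methylcytosine and so start the removal of DNA methylation, and the comparison of TKO with WT asks which transcripts differ when the 3 enzymes are lost. Reads assigned to genes came to 76670721 and 76328879 in WT replicates 1 and 2, and to 92846815 and 80228761 in TKO replicates 1 and 2. Across 21584 tested genes the WT libraries had a Pearson correlation of 0.996 (log2 CPM, across genes, which are not independent replicates), with 29 genes at least 4-fold apart. The TKO libraries were much farther from each other, with a correlation of 0.924 and 2466 genes at least 4-fold apart. TKO replicate 1 stood 4-fold or more from a WT library at 3119 to 3190 genes and TKO replicate 2 at 657 to 679 genes. TKO replicate 1 also listed 0 unaligned reads, against 10026617, 9775256 and 11478289 in WT replicates 1 and 2 and TKO replicate 2, and it had 2.28% of its gene counts on processed pseudogenes against 0.301%, 0.309% and 0.292%.

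The targeted genes differed in their transcript levels. TET1 (ENSG00000138336, chromosome 10), the most abundant of the 3 in WT, had 142 ± 4.26 counts-per-million (CPM; mean ± SD, n = 2) in WT and 46.5 ± 17.0 in TKO, with raw counts of 11094 and 10648 in WT against 3100 and 4803 in TKO replicates 1 and 2. TET2 (ENSG00000168769, chromosome 4) was higher in TKO, at 6.89 ± 1.65 CPM against 2.32 ± 0.224, and TET3 (ENSG00000187605, chromosome 2) had 36.4 ± 6.37 CPM in TKO and 37.4 ± 0.425 in WT. The log2 fold changes, TKO against WT, were -1.61 ± 0.30 (SE) for TET1, 1.57 ± 0.33 for TET2 and -0.04 ± 0.17 for TET3. The adjusted p from edgeR was 0.336 for TET1, 0.349 for TET2 and 0.928 for TET3, and from DESeq2 it was 0.00322, 0.00166 and 0.977. The log2 fold change of TET3 was 0.11 without TKO replicate 2 and -0.23 without TKO replicate 1. A mutation that ends a reading frame need not lower a transcript, and the files do not show the edited bases, so these levels check the genotypes only in part.

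Among the largest rises called by DESeq2 were the transcription factors HAND1 (heart and extraembryonic mesoderm), EOMES (mesendoderm) and SP5 (a direct WNT target). They were low in WT, at 0.0522 ± 0.0554, 0.346 ± 0.00958 and 0.0718 ± 0.00916 CPM, and had 9.74 ± 6.27, 41.8 ± 49.5 and 113 ± 152 CPM in TKO. Their counts in TKO replicates 1 and 2 were 1274 and 435 for HAND1, 6905 and 564 for EOMES, and 19797 and 457 for SP5, so TKO replicate 1 carries most of each mean. Among the genes most lowered were MX2, an interferon-induced GTPase, with 14.7 ± 1.10 CPM in WT and 0.0948 ± 0.0554 in TKO, and TDRD1, a tudor-domain protein of the germline piRNA pathway, with 7.61 ± 0.063 CPM in WT and 0.0964 ± 0.105 in TKO. The metallothionein gene MT1H had 704 and 627 counts in WT against 0 and 3 in TKO, and BHMT2, an enzyme that methylates homocysteine, had 466 and 544 counts against 0 and 5.

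**Figure D1:**
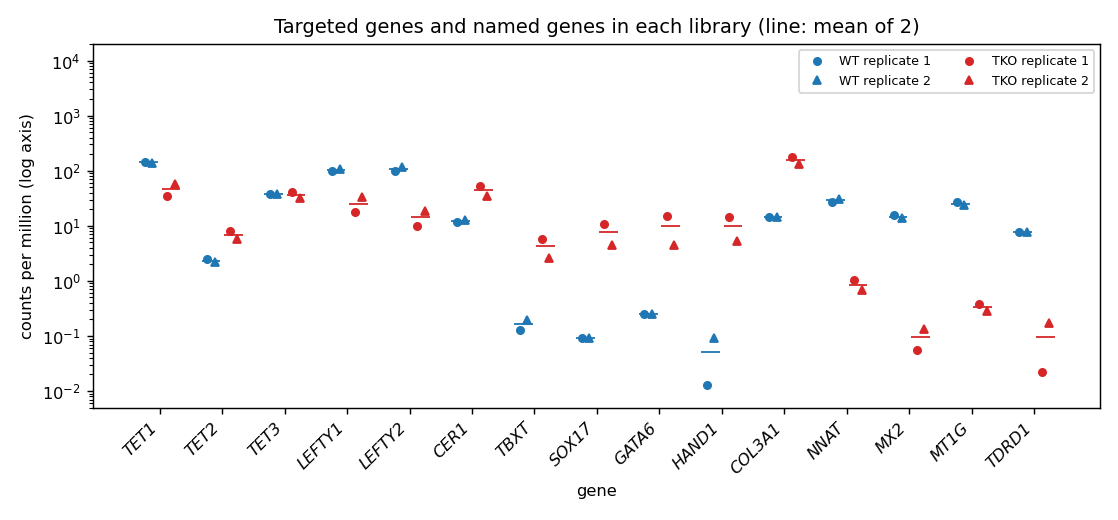
CPM on a log axis for TET1, TET2, TET3 and 12 further genes in each of the 4 libraries (circles, replicate 1; triangles, replicate 2; blue, WT; red, TKO; short lines, mean of 2). COL3A1 stood at 14.5 CPM in WT and 156 in TKO on average, while TET3 had overlapping levels of 37.4 and 36.4.

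DESeq2 called 1033 genes at an adjusted p under 0.05, 599 of them higher and 434 lower in TKO, and 972 of these changed at least 2-fold. It was run on 38673 genes, without edgeR's filter on low counts. Of its calls, 1004 were also in edgeR's fit. Among those, 453 coding genes and 75 processed pseudogenes were higher, and 340 coding genes and 8 processed pseudogenes were lower. edgeR with quasi-likelihood tests, chosen for this comparison before the data were examined, called 0 genes among 21584 (smallest adjusted p 0.319), with 2418 genes at an unadjusted p under 0.05, 1278 higher and 1140 lower, where chance alone would give 1079. limma-voom called 0 genes as well, with 2348 at an unadjusted p under 0.05. The biological coefficient of variation was 3.84% in the WT pair, 59.5% in the TKO pair and 42.1% over the 4 libraries, so the distance of TKO replicate 1 from TKO replicate 2 sets the errors. Without TKO replicate 1 edgeR called 7456 genes and DESeq2 2249 higher and 2642 lower, and without TKO replicate 2 they called 15068 genes and 5706 higher and 5492 lower. In these fits the lone TKO library was assumed to vary as little as the WT pair. Without WT replicate 1 DESeq2 called 69 genes higher and 67 lower, without WT replicate 2 it called 72 and 69, and edgeR called 0 in both cases. In simulated counts with the spread of the 4 libraries and 200 changed genes among 21584, edgeR recovered 4%, 38%, 86% and 94% of genes changed 2-, 4-, 16- and 64-fold, with 10 false calls among 121. DESeq2 recovered 16%, 82%, 100% and 98%, with 157 false calls among 305. Both simulated groups had the same spread, unlike the WT and TKO pairs here. The false share therefore cannot be carried over to the 1033 calls. In counts simulated with the spread of the WT pair, DESeq2 made 11 false calls among 208 and edgeR 18 among 217. The source records do not say whether replicates were separate cultures or clones, so each p measures only the spread between samples.

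The 24 genes with the largest DESeq2-called differences were picked by a rule set in advance for edgeR, applied with DESeq2's adjusted p after edgeR gave no gene. The 12 highest were SP5, HOXA1, EVX1, ZNF37A, HAND1, OLIG3, ANKRD1, IL7R, APLNR, CST1, LUM and EOMES. HOXA1, a hindbrain and early mesoderm HOX gene, had 2 counts over the WT pair and 3334 over the TKO pair, a ratio of 1484 (95% counting interval 411 to 12262), but 3319 of these lay in TKO replicate 1 and 15 in TKO replicate 2. EVX1, a primitive streak factor, had 1 and 0 counts in WT and 967 and 46 in TKO (ratio 902, 162 to 35661), ZNF37A had 2 and 1 against 845 and 11 (ratio 254, 86.6 to 1234), and IL7R, the interleukin-7 receptor, had 0 and 3 against 248 and 192 (ratio 131, 44.4 to 636). APLNR, the apelin receptor of early mesoderm, was at 0.111 ± 0.00935 CPM in WT and 14.4 ± 12.8 in TKO, with 2108 and 443 counts in TKO replicates 1 and 2 (DESeq2 adjusted p 1.47e-12, edgeR 0.32). OLIG3, ANKRD1, CST1 and LUM had log2 fold changes of 7.20 ± 2.19, 7.06 ± 1.60, 6.96 ± 1.13 and 6.93 ± 1.36, and for all 4 TKO replicate 1 was the higher TKO library. The 12 lowest were MT1H, ZNF844, BCL2L10, BHMT2, CYTL1, MX2, NPFFR2, TCEAL5, CST6, IZUMO2, SLC17A9 and TDRD1. MT1H had a WT to TKO ratio of 498 (170 to 2419) and BCL2L10, an apoptosis regulator of oocytes, of 354 (63.0 to 14017). ZNF844 differed between the WT libraries themselves, with 391 and 12 counts, against 1 and 0 in TKO (ratio 453, 80.8 to 17921). SLC17A9, a vesicular nucleotide transporter, had 2361 and 2299 counts in WT and 23 and 36 in TKO, a log2 fold change of -6.45 ± 0.39. CYTL1, NPFFR2, TCEAL5, CST6 and IZUMO2 had log2 fold changes of -7.30 ± 0.49, -6.71 ± 0.41, -6.60 ± 1.32, -6.48 ± 1.25 and -6.43 ± 0.94. Intervals on ratios cover counting error only.

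Genes of the germ layers lay higher in TKO as groups. In the mesendoderm and mesoderm list 14 of 29 tested genes rose and 3 fell in edgeR's test adjusted over the list alone, 0 passed over all genes, and DESeq2 called 16 higher and 2 lower. TBXT (brachyury, the primitive streak factor) had 10 and 15 counts in WT and 527 and 216 in TKO, a log2 fold change of 4.69 ± 0.65. NKX2-5, the cardiac homeobox gene, had 6 and 4 counts against 164 and 115 (4.59 ± 0.47), and HAND2 had 4 and 4 against 52 and 57 (3.57 ± 0.39). In the definitive endoderm list 13 of 23 genes rose and 1 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 10 higher and 1 lower. SOX17, a factor that specifies endoderm, had 7 counts in each WT library and 976 and 362 in TKO (6.36 ± 0.70), and GATA6, an endoderm and mesoderm factor, had 19 in each against 1372 and 365 (5.30 ± 0.82). LGR5, a receptor for R-spondins, had 29 and 23 against 422 and 258 (3.52 ± 0.43). The median log2 difference from WT was 2.69 in TKO replicate 1 and 1.51 in TKO replicate 2 for the mesendoderm list, and 2.21 and 1.48 for the endoderm list. The neuroectoderm list had a smaller shift, with a median log2 fold change of 0.80 over 34 genes (median difference from WT 0.67 in TKO replicate 1 and 0.40 in TKO replicate 2), 0 genes passing either over the list alone or over all genes, and 4 called higher by DESeq2. ZIC1, a zinc finger factor of the dorsal neural tube, had 33 counts in each WT library and 158 and 270 in TKO (2.55 ± 0.49), LHX2 and ZIC4 had log2 fold changes of 1.86 ± 0.35 and 1.87 ± 0.41, and SOX21, a repressor active in neural progenitors, had 1.28 ± 0.28. PAX6, the early neural factor, which was looked up after the data were seen, had 91 and 122 counts in WT and 106 and 132 in TKO. camera with its preset correlation of 0.01, which asks whether a list's genes lie higher than other genes, gave adjusted p of 6.51e-07 for mesendoderm, 1.25e-07 for endoderm and 6.60e-05 for neuroectoderm, adjusted over 24 lists. With an estimated correlation none of the 3 passed: the adjusted p was 0.485 for mesendoderm, 0.485 for endoderm and 0.397 for neuroectoderm.

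**Figure D2:**
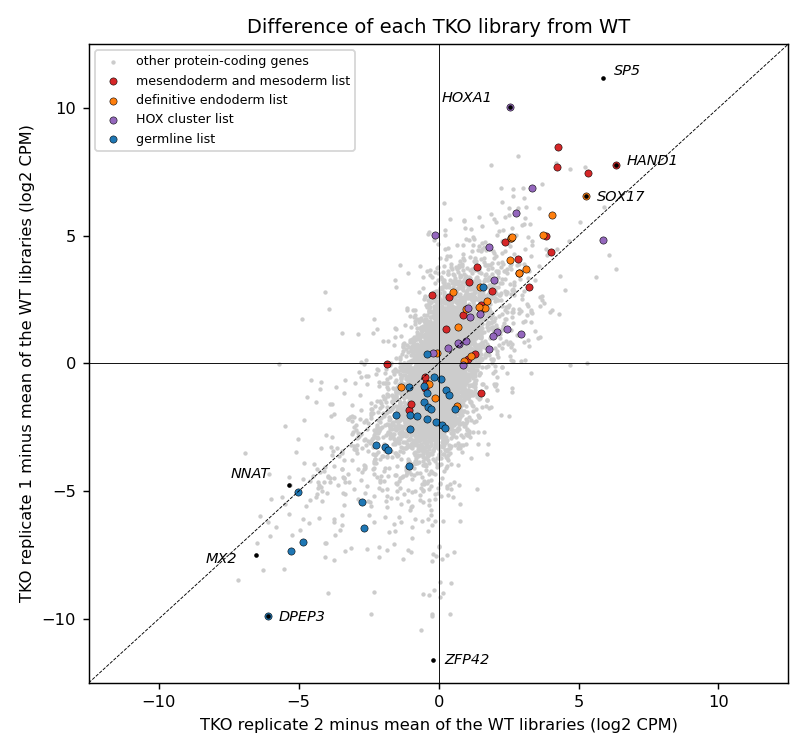
Difference of each TKO library from the mean of the WT libraries in log2 CPM, for every tested protein-coding gene (grey) and the members of 4 gene lists (colours); the dashed line marks equal differences. Genes of the mesendoderm, endoderm and HOX lists lay mostly in the upper right, and ZFP42 lay near 0 in TKO replicate 2 and at -11.62 in TKO replicate 1.

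HOX genes, which pattern the body axis, had a median log2 fold change of 1.90 over 21 tested members (1.35 in TKO replicate 1 and 1.80 in TKO replicate 2). None passed over the list alone or over all genes, and DESeq2 called 5 higher and 0 lower. With the alternative filter of 1 CPM in at least 2 libraries the HOX list could not be tested. HOXB13 had 0 and 1 counts in WT and 76 and 146 in TKO (ratio 198, 35.1 to 7842), HOXB3 had 3 and 8 against 476 and 48, HOXB8 had 17 and 15 against 77 and 51, and HOXC8 had 15 in each WT library against 67 and 37. The wider list of developmental transcription factors held 77 tested genes, of which 24 rose and 1 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 29 higher and 0 lower. TBX15, a T-box factor of limb and skin mesenchyme, had 64 and 56 counts in WT and 656 and 429 in TKO (3.00 ± 0.36), and NKX6-1, a factor of pancreas and neural tube, had 6 and 4 against 78 and 64 (3.63 ± 0.42). In the trophoblast and amnion list 3 of 18 genes rose and 1 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 4 higher and 2 lower. TFAP2A and WNT6 lay above WT (1.89 ± 0.35 and 2.83 ± 0.50), as did HAND1 (7.50 ± 1.19), while KRT7, a simple-epithelium keratin, fell from 613 and 579 counts to 151 and 66 (-2.65 ± 0.49, DESeq2 adjusted p 2.85e-05). The camera adjusted p was 8.07e-10 for HOX genes, 2.20e-14 for developmental factors and 0.00171 for trophoblast genes. With an estimated correlation the adjusted p was 0.397 for each of these 3 lists. The filter on low counts kept 21 of 39 matched HOX genes, 77 of 99 developmental factors and 18 of 31 trophoblast genes. A gene silent in WT was kept only if both TKO libraries expressed it. That selection can raise the medians and camera results of these lists, and by how much was not tested. The trophoblast call also ended with the filter of 1 CPM in at least 2 libraries (camera adjusted p 0.0515), and without TKO replicate 2.

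Germline genes lay lower in TKO. DESeq2 called 7 of the 31 tested genes lower and 1 higher, while in edgeR 0 passed over the list alone or over all genes. Of the 31 genes, 25 were at least 2-fold lower than WT in TKO replicate 1 and 14 in TKO replicate 2, with median log2 differences of -2.06 and -0.51. HSF5, a heat shock factor of spermatocytes, had 66 and 53 counts in WT and 0 in both TKO libraries, which makes it at least 44.5-fold lower (floor of 3 counts over the group). SYCP1, a protein of the synaptonemal complex, had 47 and 64 counts against 5 and 11, and SPATA22, needed for meiotic recombination, had 22 and 17 against 4 and 6. DPEP3, NKAPL and PIWIL2, picked after their values were seen, had 1805 and 1758, 241 and 238, and 2280 and 2154 counts in WT against 0 and 26, 0 and 7, and 28 and 371 in TKO. DAZL, an RNA-binding protein of primordial germ cells also picked after its values were seen, went the other way, with 281 and 280 counts in WT and 2663 and 912 in TKO (log2 fold change 2.47 ± 0.57, DESeq2 adjusted p 0.00256). The camera adjusted p was 2.07e-10, and with an estimated correlation the adjusted p was 0.518. The filter on low counts kept 31 of 53 matched germline genes. A gene silent in TKO was kept only if both WT libraries expressed it, which can lower the list's median.

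Secreted regulators of NODAL signalling differed in both directions, while the WNT genes that DESeq2 called were higher. The NODAL antagonists LEFTY1 and LEFTY2 had 103 ± 7.17 and 108 ± 12.4 CPM in WT and 25.1 ± 10.8 and 14.4 ± 6.40 in TKO, log2 fold changes of -2.03 ± 0.36 and -2.91 ± 0.39. CER1, another NODAL and BMP antagonist, was at 12.1 ± 0.524 CPM in WT and 43.9 ± 13.1 in TKO (1.86 ± 0.26), and INHBA, an activin subunit, had a log2 fold change of 1.30 ± 0.25. Of 23 NODAL and activin genes 2 rose and 2 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 4 higher and 2 lower. As a group they did not pass (camera adjusted p 0.0964, and 0.518 with an estimated correlation). Their median log2 difference from WT was 0.67 in TKO replicate 1 and 0.17 in TKO replicate 2. In the WNT list 2 of 32 genes rose and 0 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 12 higher and 0 lower. WNT5A, a non-canonical WNT ligand, had 526 and 562 counts in WT and 3979 and 2104 in TKO (2.30 ± 0.33), TCF7, a WNT-responsive transcription factor, had 0.79 ± 0.15, and DKK4, a WNT antagonist, had 2 and 0 counts against 69 and 39 (ratio 48.1, 13.0 to 402). The camera adjusted p for the WNT list was 0.000128, and with an estimated correlation the adjusted p was 0.518. The list's median log2 difference was 1.91 in TKO replicate 1 and 0.47 in TKO replicate 2.

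Stromal matrix genes, included because the cells grew on irradiated mouse fibroblast feeders, lay higher in TKO, as the germ layer genes did. COL3A1 had 14.5 ± 0.235 CPM in WT and 156 ± 30.6 in TKO (3.43 ± 0.19), FN1 had 608 ± 29.8 and 1555 ± 166 (1.35 ± 0.13), COL1A2 had a log2 fold change of 1.01 ± 0.19 and DCN of 2.35 ± 0.42. COL1A1, picked after the data were seen, had 423 ± 10.1 CPM in WT and 345 ± 66.0 in TKO (-0.29 ± 0.17). Of 31 genes 2 rose and 0 fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 10 higher and 0 lower. The camera adjusted p was 7.27e-08, and with an estimated correlation the adjusted p was 0.518. The median log2 difference from WT was 1.72 in TKO replicate 1 and 0.53 in TKO replicate 2.

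Pluripotency genes did not pass as groups. Of 35 genes of primed pluripotency 0 passed in edgeR, over the list alone or over all genes, and 0 in DESeq2, with a camera adjusted p of 0.357. SOX2 had 303 ± 10.6 CPM in WT and 378 ± 31.8 in TKO, THY1 265 ± 23.3 and 173 ± 23.3, CD9 238 ± 10.2 and 201 ± 3.69, and OTX2 27.0 ± 1.84 and 81.0 ± 56.3. ZFP42 (REX1), looked up after the data were seen, had 24619 and 24868 counts in WT and 23318 in TKO replicate 2, but 7 in TKO replicate 1. DNMT3B, also looked up then, the de novo methyltransferase that marks primed cells, had 234604 and 233783 counts in WT and 79969 and 287518 in TKO replicates 1 and 2. The direction of the primed list turned without TKO replicate 1 (camera adjusted p 0.729), and over the 4 left-out libraries its adjusted p ranged from 0.0505 to 0.729. Naive pluripotency genes had a camera adjusted p of 0.427 over 20 genes, with DESeq2 calling 1 higher, TBX3 (3.13 ± 0.68 CPM in WT and 7.25 ± 0.348 in TKO). The median log2 difference of the naive list was -2.18 in TKO replicate 1, where 11 genes were at least 2-fold lower and 3 higher, and 0.21 in TKO replicate 2. DPPA2 and TFCP2L1, picked after their values were seen, had 4218 and 4185, and 2007 and 2075 counts in WT against 271 and 3258, and 293 and 2101 in TKO replicates 1 and 2. KLF5, KLF2 and TFAP2C had log2 fold changes of 1.22 ± 0.56, 1.15 ± 0.60 and 0.26 ± 0.12, and 0 naive genes passed in edgeR over the list alone. The naive list was lower without TKO replicate 2 and turned to higher without TKO replicate 1. Only 4 of 22 cleavage stage genes could be tested, with a camera adjusted p of 0.179 and 0 genes passing in either tool. Their log2 fold changes were -0.86 ± 0.58 for ZNF280A, -1.51 ± 1.18 for TPRX1, -1.21 ± 1.48 for CCNA1 and 0.09 ± 0.41 for SLC34A2, which turned negative without WT replicate 1 (-0.10) or TKO replicate 1 (-0.26).

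Imprinted genes moved singly and not as a group (camera adjusted p 0.874 over 40 genes). NNAT, expressed from the paternal copy, fell from 29.0 ± 2.10 to 0.858 ± 0.249 CPM (log2 fold change -5.07 ± 0.32) and was the 1 gene that passed in edgeR adjusted over the list alone, with 0 over all genes. DESeq2 called 4 imprinted genes higher and 2 lower. PLAGL1 and IGF2 were higher, with 36 and 37 counts in WT against 1471 and 242, and 309 and 340 against 3993 and 1209. WT1, the Wilms tumour gene, had 0.274 ± 0.0372 CPM in WT and 0.920 ± 0.388 in TKO. H19, picked after the data were seen, had 41 and 23 counts in WT and 19 in TKO replicate 2 but 4657 in TKO replicate 1. The direction of the list turned without any one of WT replicate 1, WT replicate 2 or TKO replicate 1 (camera adjusted p 0.795, 0.870 and 0.729).

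In the list of the DNA methylation machinery, which leaves out the TET genes, none of 25 genes passed in either tool (camera adjusted p 0.435), with DNMT1, the maintenance methyltransferase, at 235 ± 1.78 CPM in WT and 274 ± 20.1 in TKO, and MECP2 and ZBTB33, which read methylated DNA, at log2 fold changes of 0.36 ± 0.11 and 0.30 ± 0.16. GADD45B had 827 and 900 counts in WT and 5731 in TKO replicate 1 but 715 in TKO replicate 2, and its direction turned without TKO replicate 1 (log2 fold change -0.37). Of 37 Polycomb genes 0 passed over the list alone or over all genes in edgeR and 1 was called higher by DESeq2, BCORL1, a corepressor, with 6.63 ± 0.154 CPM in WT and 17.4 ± 2.50 in TKO. AEBP2, ASXL1 and EED had log2 fold changes of 0.42 ± 0.09, 0.50 ± 0.12 and 0.52 ± 0.13 (camera adjusted p for the list 0.0719).

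The interferon response list held 35 tested genes and did not pass (camera adjusted p 0.0719, lower). MX2, with 1183 and 1065 counts in WT and 5 and 11 in TKO, was the 1 gene that fell adjusted over the list alone, 0 passed over all genes, and DESeq2 called 2 lower. The other was MX1, its neighbouring paralogue, with 541 and 552 counts against 32 and 87 (-3.33 ± 0.67). IFITM3 had 291 ± 13.9 CPM in WT and 186 ± 15.7 in TKO, and OAS1 went the other way, from 7 and 9 counts to 36 and 52. The interferon list's median log2 difference from WT was -0.31 in TKO replicate 1 and -0.10 in TKO replicate 2. Its direction stayed lower with each library left out, and with an estimated correlation its adjusted p was 0.677. Cholesterol synthesis genes had a camera adjusted p of 0.0719 over 31 genes, with 0 past edgeR's threshold over the list alone or over all genes. DESeq2 called 2 lower: FDFT1, squalene synthase, at 515 ± 27.4 CPM in WT and 325 ± 4.17 in TKO, and PCSK9, which degrades the LDL receptor, at 602 ± 4.65 and 185 ± 110. MSMO1 and HSD17B7 had log2 fold changes of -0.32 ± 0.10 and -0.64 ± 0.24. The list's median log2 difference from WT was -0.03 in TKO replicate 1 and -0.21 in TKO replicate 2. With an estimated correlation its adjusted p was 0.606.

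Many immediate early and stress genes, though not all, lay well above WT in TKO replicate 1 and not in TKO replicate 2. Of 20 genes 14 were at least 2-fold above WT in TKO replicate 1 and 0 in TKO replicate 2, with median log2 differences of 1.57 and -0.15. EGR3 had 57 and 83 counts in WT, 6498 in TKO replicate 1 and 84 in TKO replicate 2, and was the 1 gene called by DESeq2. KLF6, ATF3 and HSPA1A had log2 fold changes of 1.28 ± 0.52, 1.38 ± 0.70 and -0.55 ± 0.23, and 0 genes passed in edgeR over the list alone or over all genes. The list did not pass (camera adjusted p 0.109). With an estimated correlation its adjusted p was 0.683. The list was lower without TKO replicate 1 and higher without TKO replicate 2, WT replicate 1 or WT replicate 2.

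**Figure D3:**
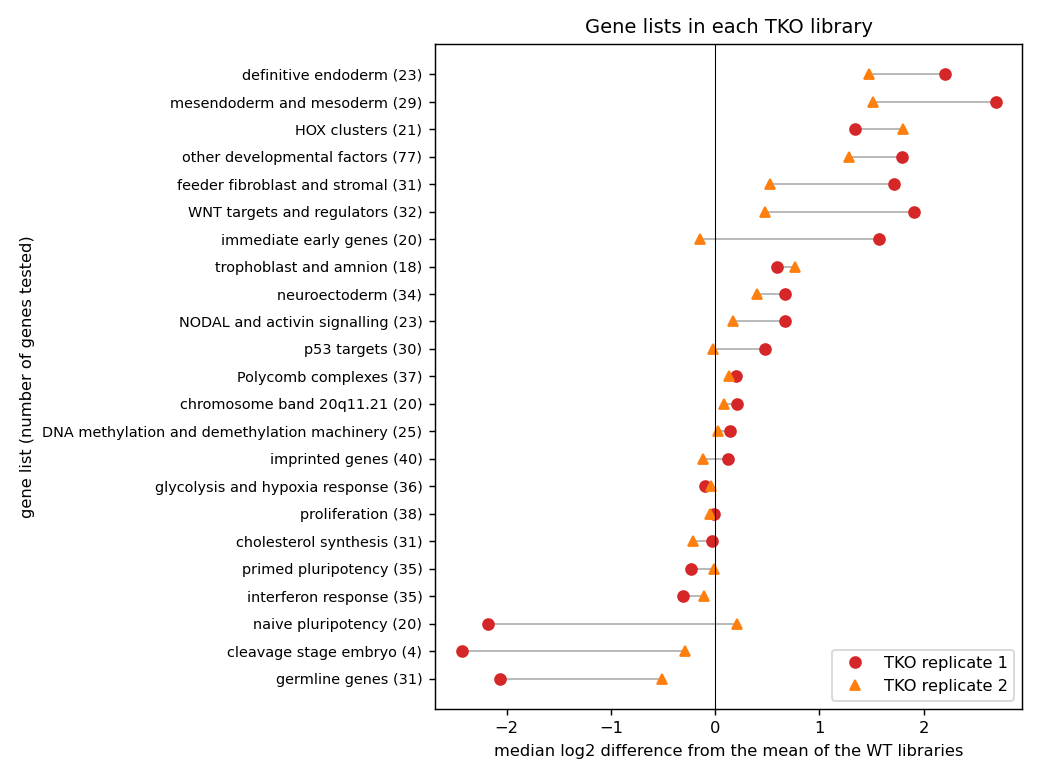
Median log2 difference from the mean of the WT libraries for 23 gene lists in TKO replicate 1 (circles) and TKO replicate 2 (triangles), with the number of genes tested in brackets. The endoderm list stood at 2.21 and 1.48, while the immediate early list stood at 1.57 in TKO replicate 1 and -0.15 in TKO replicate 2.

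The lists for cell division, metabolism and genome stress did not pass, and in each 0 genes passed in edgeR, over the list alone or over all genes, and 0 in DESeq2. For 38 proliferation genes the camera adjusted p was 0.685, with CENPE, a kinetochore motor, at 64.5 ± 1.73 CPM in WT and 95.7 ± 7.21 in TKO and CDT1, MCM4 and CENPF at log2 fold changes of -0.35 ± 0.09, 0.36 ± 0.12 and 0.26 ± 0.09. For 36 genes of glycolysis and hypoxia it was 0.654, with HK2 at 82.5 ± 0.583 and 120 ± 2.45 CPM, HK1 at 614 ± 21.8 and 366 ± 81.2, and BNIP3L and KDM3A at -0.33 ± 0.09 and 0.32 ± 0.11 on the log2 scale. In both lists the median (-0.06 in each) and the mean (0.02 and 0.09) differed in sign. For 30 p53 targets it was 0.316, with CDKN1A, the cell cycle inhibitor, at 71.0 ± 0.348 and 49.4 ± 2.60 CPM and RRM2B, FAS and BTG2 at log2 fold changes of -0.48 ± 0.09, 0.81 ± 0.30 and 1.58 ± 0.64. The p53 list was higher without TKO replicate 2 and its direction turned without TKO replicate 1. For 20 genes of chromosome band 20q11.21, often gained in cultured human embryonic stem cells, it was 0.262, with a median log2 fold change of 0.16 and a mean of -0.10. Its member COX4I2 had 15 and 19 counts in WT and 0 and 1 in TKO (WT to TKO ratio 38.2, 6.41 to 1552), and KIF3B and NOL4L had 0.45 ± 0.12 and 0.30 ± 0.14. The test of histone genes without a poly(A) tail was void, since 15 of 37 symbols matched. Its adjusted p was 0.268, with H1-5 at 1.06 ± 0.0195 and 0.529 ± 0.00936 CPM. Mitochondrially encoded transcripts were listed at 0 in every library and were not tested.

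Genes grouped by chromosome did not pass as sets, with 0 of 23 past the threshold (camera, adjusted over the chromosomes). Chromosome 19 had the smallest adjusted p (0.216, lower), and its direction stayed lower with each library left out.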

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

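The estimator, prior and coding-gene alternatives, and all alternatives for DESeq2, were chosen after the data were seen. edgeR's count of 0 genes held under relative log expression, upper quartile, both filters, limma-voom, the replicate term, the newer estimator, the robust prior and coding genes alone. It moved with DESeq2 (1033 genes, 599 higher, 434 lower, 972 at least 2-fold) and over the fits that leave out 1 library, which ranged from 0 to 15068 genes (0 to 7600 higher, 0 to 7468 lower, 0 to 7708 at least 2-fold). The values were 0 without either WT library, 7456 without TKO replicate 1 and 15068 without TKO replicate 2, where the TKO pair's spread no longer enters. For DESeq2 the same fits gave 69 to 5706 genes higher and 67 to 5492 lower, and the replicate term gave 313 higher and 327 lower, while coding genes alone gave 622 and 390. Of the genes DESeq2 called in 4 libraries, 418 higher and 414 lower were called in the same direction without TKO replicate 1. Chromosome sets ranged from 0 to 1 (chromosome 19) over the left-out libraries. The 9 lists that passed with the preset correlation all failed with an estimated one, at an adjusted p of 0.397 (HOX, developmental factors, neuroectoderm, trophoblast), 0.485 (mesendoderm, endoderm) or 0.518 (germline, stromal, WNT). The estimate was -0.007 for HOX, -0.02 for neuroectoderm and -0.05 for trophoblast genes, below the preset 0.01. A higher correlation is therefore not why these lists failed. For the others it ran from 0.09 (developmental factors) to 0.71 (stromal). The 9 lists failed with fry's directional test too, at 0.0961 (HOX, trophoblast), 0.0996 (neuroectoderm), 0.141 (developmental factors), 0.167 (endoderm), 0.182 (mesendoderm), 0.205 (germline) and 0.357 (stromal, WNT), and the cause was not tested. fry's mixed test, for change in either direction, passed for HOX and trophoblast genes (adjusted p 0.0447 each). With 1 CPM in 2 libraries the trophoblast list no longer passed (0.0515), Polycomb (0.0390) and interferon (0.00787) passed, and imprinted (0.834) and histone genes (0.948) turned. The HOX list could not be tested with that filter. With the replicate term interferon (0.0310) and immediate early genes (0.0338) passed and imprinted genes turned (0.952), as they did with fry (0.968). Over the 4 fits that leave out 1 library, the adjusted p of some lists changed side or direction, and the cause was not tested. In each of these fits 1 group held a single library. The adjusted p given for them therefore carry no replication within that group. Without TKO replicate 1 primed (0.729; 0.0505 at the other end of the range), naive (0.764), imprinted (0.729), p53 (0.258; up to 0.345 without WT replicate 2) and immediate early genes (0.0341) turned and cholesterol genes passed (6.84e-05; up to 0.588). Without TKO replicate 2 naive (0.0284), NODAL (0.0246; up to 0.618), p53 (0.0127), interferon (0.00799; up to 0.0761) and immediate early genes (0.000189) passed and trophoblast genes did not (0.0717; as low as 0.00241). Without WT replicates 1 and 2 interferon (0.0412, 0.0407) and immediate early genes (0.0412, 0.0424) passed and imprinted genes turned (0.795, 0.870). Of 114 named genes 3 turned: TET3 without TKO replicate 2 (log2 fold change 0.11, range from -0.23), GADD45B without TKO replicate 1 (-0.37, range to 2.48) and SLC34A2 without WT replicate 1 (-0.10) or TKO replicate 1 (-0.26, range to 0.34). Apart from the TET genes, the 114 were picked by their difference or p in these same libraries. Their steadiness over the fits is therefore no independent check. Depth limits the ratios on 1 to 3 counts, whose intervals span more than 4-fold.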

Other observations

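Apart from camera results, which repeat the list tests above, the tests reported here were chosen after the results they bear on had been seen. Excepted are those that relate pseudogene excess to parent level and add pseudogene counts to the near-absent genes, which were written down before their results. MT1G, VIM, SPARC, UTF1, RPL39P3, ZFP42, IRAK4, POLE4, POU5F1, DPPA4, TDGF1 and PODXL are outside the rule for named genes and were picked after their values were seen.

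Beyond the lists, the TKO libraries shared a block of large differences. Of 15463 coding genes, 155 were at least 4-fold higher than the WT mean in both TKO libraries and 201 at least 4-fold lower, which covers 68.0% and 80.4% of those so changed in TKO replicate 2 and 23.8% and 18.9% of those in TKO replicate 1. A shared WT mean raises such an overlap, so each TKO library was also set against the WT library of its own number: the overlap was then 15.1 times that of independent lists for higher genes (144 genes) and 11.5 times for lower genes (200 genes). Genes such as MT1G, a metallothionein with 2037 and 1825 counts in WT and 34 and 23 in TKO, and MX2 belong to the lower block. These genes are candidates for effects that follow the genotype, although the WT and TKO libraries also differ in any clone or culture history that the source records leave out.

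Some abundant transcripts differed in level between the TKO libraries. VIM, which encodes vimentin, had 10451 and 12215 counts in WT, 108887 in TKO replicate 1 and 20859 in TKO replicate 2, and SPARC had 45087 and 46134 against 104874 and 49953. UTF1, a pluripotency-associated chromatin factor, had 4433 and 4677 counts in WT, 360 in TKO replicate 1 and 2866 in TKO replicate 2.

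Processed pseudogenes were high in TKO replicate 1 alone. Of 2014 tested, 748 (37.1%) were at least 4-fold higher than in TKO replicate 2, against 2.45% of coding genes. RPL39P3, for example, had 318 and 308 counts in WT, 25254 in TKO replicate 1 and 298 in TKO replicate 2. Transcription following the genotype is argued against by the 0.292% of counts on pseudogenes in TKO replicate 2 (0.301% and 0.309% in WT). Reads outside genes were 6.31% in TKO replicate 1 and 9.71% or more in the others. That lower share goes against genomic DNA only if this library was aligned as the others were, which is not known. For reads of spliced genes placed on their processed pseudogenes, as by a different alignment of this library, the tests disagreed, and the explanation stays open. In its favour, 131 parent genes had pseudogenes that gained at least 10% of the parent's level. These parents lay lower in TKO replicate 1 than 317 parents without gain, by a difference of -0.37 log2 units (permutation p 1e-05, the smallest the permutations can give, two-sided). Parent and pseudogenes summed to medians of 0.13 and 0.12. Part of that match is built in, since the groups were chosen by the gain and adding it had to raise the first median. Against the explanation, the excess had a rank correlation with the parent's level of 0.00436, where the bound written down first asked for more than 0.3. The gain in CPM had a rank correlation of 0.08, and within TKO replicate 2 the levels of pseudogene and parent had 0.15. The share a pseudogene takes also depends on its likeness to the parent, which was not measured, so these low values do not settle it.

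At 32-fold or more below each other library, 32 coding genes were nearly absent from TKO replicate 1 alone, among them ZFP42, IRAK4 (1301 and 1273 counts in WT, 1 and 1237 in TKO) and POLE4 (1411 and 1415 against 7 and 1860), while 0 genes were so in any other single library. Their omission from counting is argued against, since 15.6% had exactly 0 reads. By the way the 32 were chosen, their near-absence is not shared by TKO replicate 2, so for them it does not follow the genotype alone. For a wider set a loss that follows the genotype stays open. Of 90 coding genes as far below WT in TKO replicate 1, chosen without TKO replicate 2, 38 were within 2-fold of WT in TKO replicate 2. In that library 11 of the 90 were nearly absent too (median of the 90 -1.39 log2 units). Loss of reads to pseudogenes of the same gene stays open too. Adding pseudogene counts brought 0% of the genes within 4-fold, but 0 of the 32 had a tested pseudogene named after them. A pseudogene with reads in TKO replicate 1 alone would not have passed the filter on low counts. The test could therefore not have found it. Zinc finger genes named ZNF made up 31.3% of the 32 (Fisher's exact test, two-sided, p 2.45e-08). Among the 11103 coding genes that could have entered they made up 3.09%. On chromosome 19 lay 37.5% of the 32 against 7.11%, an excess that overlaps the first since 8 of the 10 ZNF genes lie there. The test treats genes as independent, and all 32 come from 1 library, so its p can overstate the evidence. Silencing of these genes in the cells of TKO replicate 1, by culture or clone, may be worth a look and was not tested.

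Of the 83 genes of the 3 germ layer lists, 33 were at least 2-fold above WT and 2 at least 2-fold below it in both TKO libraries, with median log2 differences of 1.41 and 0.91 in TKO replicates 1 and 2, although with an estimated correlation the mesendoderm, endoderm and neuroectoderm lists did not pass (adjusted p 0.485, 0.485 and 0.397). The way TKO replicate 1 was processed is argued against as the whole cause, because in TKO replicate 2 their median lay 0.92 log2 units above that of all coding genes (bootstrap 95% interval 0.53 to 1.48, which treats the genes as independent), against -0.01 between the WT libraries. A share of differentiated cells among the TKO cells cannot be told apart from a change in every cell. The primed pluripotency list had a median log2 difference of -0.23 in TKO replicate 1 and -0.0113 in TKO replicate 2. POU5F1 was at -1.13 and -0.29, DPPA4 at -1.17 and -0.43, TDGF1 at -1.72 and -0.33 and PODXL at -0.75 and -0.26. Other members rose in both TKO libraries, among them SOX2 (0.23 and 0.40) and OTX2 (2.16 and 0.61). Of the list's 35 genes, 5 were more than 2-fold above WT and 10 below it in TKO replicate 1. In TKO replicate 2 these counts were 1 and 0. A small share of other cells need not lower abundant transcripts by a measurable amount. Feeder fibroblast RNA also stays open for the stromal genes, since genes abundant in fibroblasts disagreed. The feeders were mouse cells and the genome build was human. Abundance in fibroblasts therefore need not tell which genes feeder reads would raise. COL1A1 was at -0.29 ± 0.17 (SE) while COL3A1 was at 3.43. In TKO replicates 1 and 2 COL1A1 lay below WT, at -0.11 and -0.50. That outcome was written down, after the data were seen, as going against feeder RNA. COL1A2 (1.22 and 0.77), VIM (3.04 and 0.78) and SPARC (0.97 and 0.03) lay above WT instead. The high level of COL1A1 in WT could also hide a small share. Loss of the TET enzymes in the stem cells themselves remains an open hypothesis beside these.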
